A study of Homo sapiens and Mus musculus with 3 samples.

How the data were processed

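TAB-seq libraries of genomic DNA from E14 mouse and H1 human embryonic stem cells were analysed from the tables the authors deposited. Per the labels' protocols, DNA was sheared, glucosylated with β-glucosyltransferase to protect 5hmC, oxidised with recombinant mouse Tet1, ligated to methylated adapters, size-selected, treated with bisulfite and amplified by PCR, with a 5mC conversion control spiked in before shearing. The shearing instrument differed between the lines, a Covaris for E14 and a Biorupter for H1, so instrument and line cannot be told apart. Bowtie, Picard and SAMtools are named in the submitters' processing notes, without versions, along with the builds mm9 and hg18. The role of each tool is not given in the sources used here.

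The list of called sites of each line gives, per the file headers, the chromosome, strand, position and context of each cytosine. Per the text deposited with the lists, the authors searched only cytosines already called methylated by methylC-Seq or BS-Seq and counted base calls with a Phred score of at least 20. They tested each cytosine with a binomial distribution at the 5mC non-conversion rate, given as 2.22% for H1, and estimated the false discovery rate from 10 random samplings. The deposited counts are raw numbers of cytosine calls and of cytosine plus thymine calls at a position. The deposited percent is the count of cytosine calls over that total, and recomputing it from the counts gave the same value to within 5e-05. The rate used for E14, and any p-value per site, were not used here.

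Each line also has a track per strand. The authors deposited these levels as a fraction between 0 and 1 on the plus strand, and with the sign reversed on the minus strand, where the sign marks the strand and was removed here. These tracks hold only positions above 0, with no context and no depth, so no counts were inferred from them and their depth is unknown. The E14 tracks gave the level of the called list at 100% of the listed called sites, within 0.0001 percentage points. The H1 tracks did so at 54.7%, so they came from another set of reads or filters, which the sources used here do not describe.

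The 2 lines were each analysed alone, because each had 1 library with tables, and they were set side by side without a test. Shares of sites have exact (Clopper-Pearson) 95% intervals, counts per region have exact Poisson intervals, and the mean listed level and the ratio of X to autosomes have percentile intervals from 1000 bootstrap draws of 1 Mb blocks. CpG dyads pair a plus-strand cytosine with the minus-strand cytosine at the next position. Dyads called on both strands at a depth of at least 10 on each were tested with a two-sided Fisher's exact test on the counts, with Benjamini-Hochberg adjustment within the line. The test was checked on simulated data with 200 dyads of known difference planted among the real depths. For clustering, called sites were placed 100 times at random among listed positions of the same chromosome and strand. Density per chromosome used the span from the first to the last listed position. The Y chromosome was left out of all results by chromosome or window.

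The rule for named regions was set before the data were examined. It took, for each line, the 10 densest and 5 sparsest 100 kb windows among those with at least 50% of the median number of listed positions, with ties ordered by listed positions, and the 5 called sites with the highest lower bound of the exact binomial interval of the level. Planned results on genes and annotated features were not run, because the gene table at hand is of another human build and no coordinates were converted. The levels of dyad partners, the equal-level simulations, the correlation of neighbouring levels with its Fisher z intervals, the level by local density and on X relative to called CG sites of the same depth, the shares outside CG without deep or edge sites, the levels beside sites outside CG, the chromosome ends and the depth by segment were not part of the planned results and were added after the data had been seen. For the equal-level simulations the call floor at each depth was the lowest number of cytosine calls in E14 and the most common number in H1.

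Alternatives covered a depth of at least 20, a shared depth of 15 to 25, autosomes alone, pooled reads, an adjusted p under 0.01, a distance of 500 bp, dyads counted once, density per listed position and other clustering backgrounds. Their effect is given in the closing section. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the random seed was 20261.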

Results

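5-hydroxymethylcytosine (5hmC), an oxidised form of 5-methylcytosine (5mC) made by the TET enzymes, was measured at single-base resolution in embryonic stem cells of mouse and human. E14Tg2A (E14) is a mouse line of strain 129/Ola, grown here without feeder cells and with LIF, and H1 is an established human line grown on Matrigel. In Tet-assisted bisulfite sequencing (TAB-seq), 5hmC is shielded with glucose, 5mC is oxidised by recombinant Tet1, and bisulfite then converts all but the shielded bases, so that a cytosine still read as C marks 5hmC. The series held 3 samples, of which 1 library of each cell line was analysed and a paired-end H1 sample was not analysed here. Median depth at called 5hmC cytosines was 30 base calls in E14 (quartiles 21 and 41) and 34 in H1 (quartiles 26 and 43). With 1 library per line there were no replicates and no test between lines, and differences between E14 and H1 compare these libraries. All intervals are 95% intervals. The exact intervals cover counting error only, and the block bootstrap intervals also cover variation between regions of the genome. None covers variation between libraries. Reads amplified by PCR without molecular identifiers may not be independent molecules, in which case the exact intervals are too narrow.

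The first comparison asked how many cytosines carried 5hmC in each line and in which sequence context. In E14, 2057636 cytosines were called, and in H1, 691414 were called. Nearly all lay in CG dinucleotides, the main target of mammalian DNA methylation, with 98.7% of the E14 sites (2031020) and 99.9% of the H1 sites (690677). Sites outside CG made up 1.29% of the E14 list (exact interval 1.28% to 1.31%) and 0.107% of the H1 list (0.0990% to 0.115%). Of the E14 sites outside CG, 18822 were in CHH and 7794 in CHG, where H is any base but G. H1 had the opposite order, with 249 in CHH and 488 in CHG. The plus strand held 50.0% of the called sites in each line, 1028782 in E14 and 345379 in H1. A two-sided exact binomial test against an even split gave p = 0.961 in E14 and p = 0.431 in H1, or 0.961 and 0.862 after Benjamini-Hochberg adjustment over the 2 lines. At the false discovery rates given with the lists, 4.84% and 5.02%, about 99590 E14 calls and 34709 H1 calls would be false. The search was limited to cytosines already called methylated by standard bisulfite sequencing, so context shares and totals also carry the content of those earlier maps.

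The second comparison concerned the share of reads with 5hmC at each called cytosine. A typical called site was hydroxymethylated in a minority of reads in both lines. The median level was 24% in E14 (quartiles 18.2% and 32.6%) and 20.0% in H1 (quartiles 16.7% and 25.0%). Levels of 50% or more occurred at 136515 E14 sites, 6.63% of the list (exact interval 6.60% to 6.67%), and at 5551 H1 sites, 0.803% (0.782% to 0.824%). Among sites with a depth of 15 to 25, a window shared by both lines, the median was 28.6% in E14 and 25.0% in H1. Median depth inside the window was 20 in E14 and 22 in H1, so depth was not fully matched. Sites at 50% or more were 7.42% of the E14 sites and 0.544% of the H1 sites in that window. The contexts differed little at that depth in E14, with medians of 28.6% in CG, 28.6% in CHG and 27.9% in CHH. In H1 the same medians were 25.0%, 23.1% over 94 CHG sites and 25.0% over 54 CHH sites. Levels fell steeply with depth in both lists, and so did the lowest level that was called. In E14 it was 40% at a depth of 10, 25% at 20 and 12% at 50, and in H1 it was 30%, 15% and 10%. Few H1 sites were that low, as 0.899% of its CG sites had the lowest cytosine count of their depth, beside 30.5% in E14. The most common cytosine counts at these depths were 4, 5 and 6 in E14 and 4, 5 and 7 in H1. The medians describe called sites at the depths reached and not cytosines in general.

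**Figure D1:**
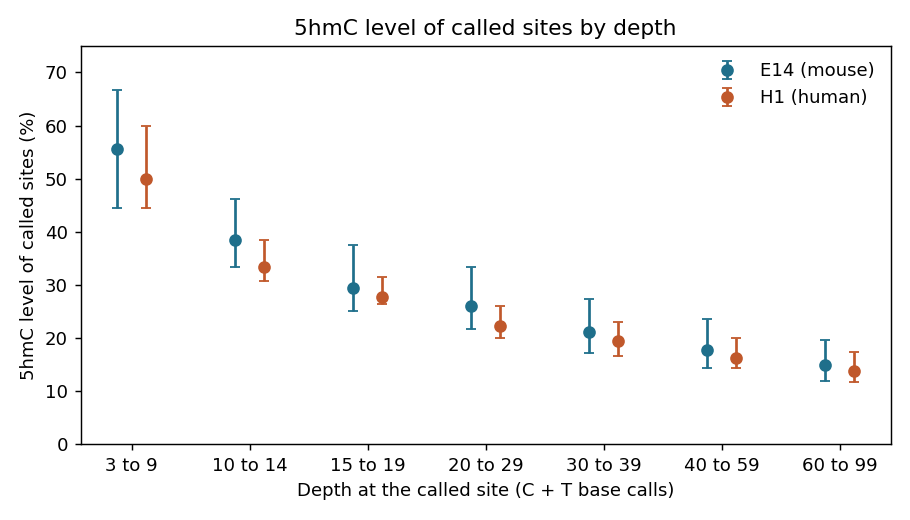
The 5hmC level of called sites (vertical axis, %) is plotted against the depth at the site (horizontal axis, cytosine plus thymine base calls, in 7 classes), with points for the median and bars for the quartiles over sites, in E14 and H1. The E14 median falls from 55.6% at depths of 3 to 9 to 14.9% at depths of 60 to 99, and the H1 median falls from 50.0% to 13.8%.

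Beyond the called lists, each library came with tracks that list cytosines with a level above 0, called or not. E14 had 34170344 such listed cytosines with a mean level of 11.6% (block bootstrap interval 11.5% to 11.7%) and a median of 7.89%. H1 had 105690367 with a mean of 4.46% (4.45% to 4.48%) and a median of 3.70%. Cytosines at 0 and the depth behind each level are absent from these tracks, so the means are not genome-wide 5hmC levels, and depth alone can move them. The E14 plus track kept called sites with a depth of 4 or less, which the E14 minus track and both H1 tracks left out. The mean listed level in E14 was 12.1% on plus and 11.1% on minus. On E14 chromosomes 6 and 8, where called sites had a median depth of 42, the median listed level was 5.71% and 5.88%. On the other E14 autosomes it lay between 7.69% on chromosome 11 and 8.51% on chromosome 14.

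The third comparison asked whether both cytosines of a CpG dyad, the plus-strand cytosine and its minus-strand partner at the next base, carried 5hmC together. They mostly did not reach a call together. Of the called CG sites, 13.4% in E14 and 21.0% in H1 had a called partner. In E14, 136084 dyads were called on both strands, 7.18% of the 1894936 dyads with any called cytosine. In H1 there were 72549, 11.7% of 618128. The share with a called partner moved little with the site's own level in E14, from 12.3% below a level of 20% to 14.8% at levels of 40% to 60% and 13.3% at 60% or more. In H1 it was 16.3% below 20% and 30.5% at levels of 30% to 40%, but 11.4% at 60% or more, over 2092 sites. Levels of called sites fell with depth, so these classes also differ in depth. Depth was not matched between them, and neither trend can be read as a link or lack of link between strands. Partners at a level above 0 were found for 44.6% of the called E14 CG sites and 78.2% of the H1 sites. Where the partner was listed, its median level was 11.4% in E14 beside 24.4% at the called cytosine, and 11.1% in H1 beside 20.0%. Called cytosines were selected for their level and partners were not, and the H1 partner levels came from another set of reads or filters than the H1 list.

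Among dyads called on both strands, levels on the strands were compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over all dyads with a depth of at least 10 on each strand. In E14, 1719 of 130302 dyads differed at an adjusted p under 0.05, with the plus cytosine higher in 855 and the minus cytosine higher in 864. The count was 1134 with a depth of at least 20 and 460 at an adjusted p under 0.01. The median difference among those dyads was 47.8 percentage points. In H1, 0 of 71994 dyads passed, and 1237 (1.72%) had an unadjusted p under 0.05, beside 14529 (11.2%) in E14. Over all tested dyads the median difference between strands was 9.31 points in E14, above the 6.67 to 6.74 points of 20 simulations with equal levels on both strands. In H1 it was 5.69 points, below all of its simulations at 5.83 to 5.93 points. The H1 simulations used another rule for the call floor than those of E14 and gave more noise than the data held. They therefore cannot show whether the H1 strands differed, and the lines cannot be compared by them. The test and the simulations treat reads as independent molecules, so the E14 excess was judged against counting noise alone. Depth limited this test, and so did the choice of dyads. It drew only on dyads called on both strands, 7.18% of those with a called cytosine in E14 and 11.7% in H1. Dyads called on 1 strand alone, where levels may differ more, were not tested. The count of 0 in H1 therefore does not show that its strands were equal. In simulated data a difference of 20 points was recovered in 0% of the E14 dyads and 1% of the H1 dyads, and a difference of 40 points in 14% and 28.5%. The 200 planted dyads had a lower strand under the lowest called level at a depth of 20 in either line, and no call floor was applied. They were also fewer than the 1719 E14 dyads that passed. These shares therefore do not give the share of real differences missed, and differences may have been missed in both lines.

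The fourth comparison asked whether called sites lay near one another. They did in both lines when set against cytosines drawn at random from the listed positions. In E14, 46.8% of the called sites had another called site, other than the dyad partner, within 100 bp, and 100 random placements gave 21.4%, a ratio of 2.18. In H1 the share was 49.1% and the placements gave 6.74%, a ratio of 7.29. Within 500 bp the ratios were 1.24 in E14 and 2.70 in H1. Such a ratio cannot exceed 100% over the chance share, which was the higher in E14 at each distance, so the ratios do not rank the lines. This background mixes CG with other cytosines, while called sites were nearly all in CG. Called dyads listed on both strands, thinned 10-fold at random, were therefore set against all CpG dyads listed on both strands, a background chosen after seeing the data. The ratio was then 1.45 in E14 and 5.83 in H1. Only 40.6% of the called dyads in E14 and 75.2% in H1 were listed on both strands and entered this comparison. With every called dyad thinned and set against the same background, the ratio was 0.835 in E14, the other direction, and 4.75 in H1, but observed and placed dyads then come from different pools of CpGs.

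The fifth comparison was of 5hmC density along the chromosomes. In E14 (build mm9), chromosome 11 was the densest with 1217 called sites per Mb, followed by chromosome 8 with 1072 and chromosome 19 with 1056, and chromosome 14 was the sparsest autosome with 579. In H1 (build hg18), chromosome 22 led with 531 called sites per Mb, ahead of chromosome 17 with 452 and chromosome 19 with 392, and chromosome 4 was lowest among autosomes with 153. The order at the top in H1 was the same per listed position, with 10.7 called sites per 1000 listed positions on chromosome 22, 9.65 on chromosome 17 and 8.65 on chromosome 19. In E14 chromosome 11 stayed first at 74.1 per 1000, while chromosome 8 ranked lower at 58.0 per 1000. Median depth at called sites was 42 on E14 chromosomes 6 and 8, against 28 to 30 on the other autosomes and 32 to 35 on the autosomes of H1.

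**Figure D2:**
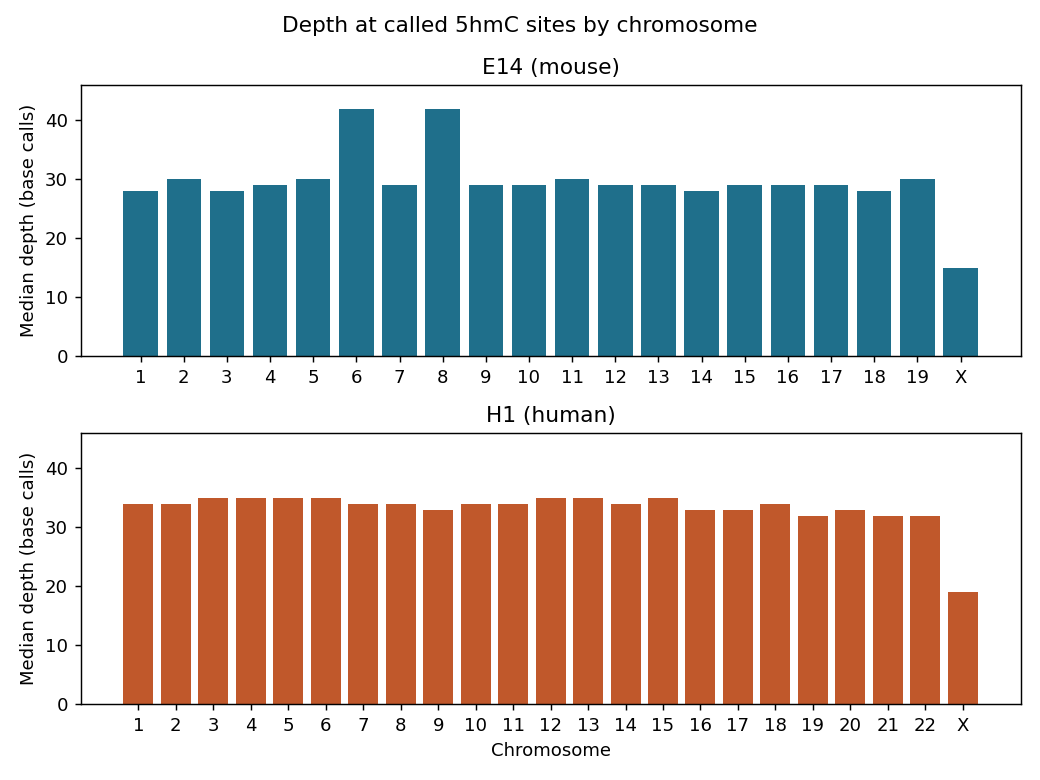
Bars give the median depth at called 5hmC sites (vertical axis, cytosine plus thymine base calls, starting at 0) for each autosome and X (horizontal axis) in E14 and H1. E14 chromosomes 6 and 8 stand at 42 above the other E14 autosomes at 28 to 30, and X is lowest in both lines, at 15 in E14 and 19 in H1.

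The X chromosome was sparse in both lines. E14 had 194 sites per Mb on X and 839 on the autosomes, a ratio of 0.231 (block bootstrap interval 0.201 to 0.268). H1 had 74.0 and 244, a ratio of 0.304 (0.261 to 0.356). Per listed position the ratios rose to 0.650 in E14 and 0.793 in H1. Both lines carry a single X chromosome, and median depth at called X sites was 15 in E14 and 19 in H1. Counting only sites with a depth of at least 20, the ratios were 0.0924 and 0.166. Relative to the mean of called CG sites of the same depth, a measure added after seeing the data, the mean difference of levels on X was 1.93 percentage points in E14 (SE 0.0704) and -0.0446 points in H1 (SE 0.0551), with errors that count sites as independent. In the depth window of 15 to 25 the medians on X were 30.4% in E14, beside 28.6% on autosomes, and 26.3% in H1, beside 25.0%. Depth still differed inside that window, with medians of 18 on X and 20 on autosomes in E14 and of 19 and 22 in H1.

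**Figure D3:**
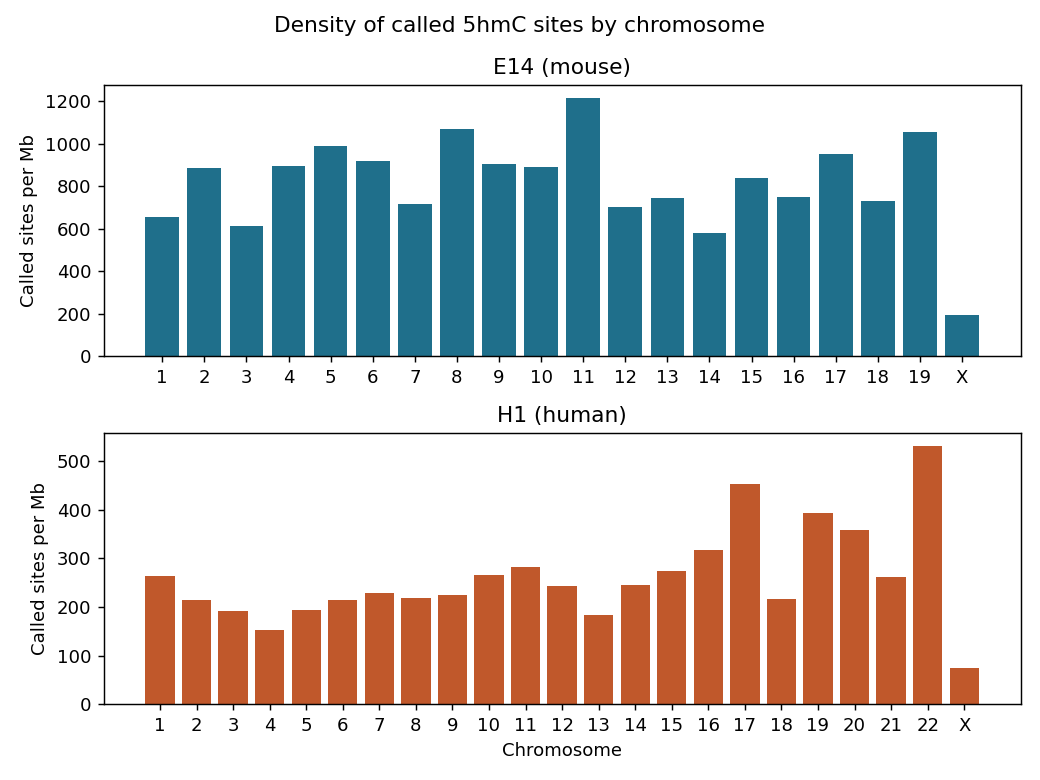
Bars give called 5hmC sites per Mb of sequence spanned (vertical axis, starting at 0, on a separate scale for each line) for each autosome and X (horizontal axis) in E14 and H1. In E14 chromosome 11 is highest at 1217 sites per Mb, in H1 chromosome 22 is highest at 531, and X is lowest in both.

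Called sites were concentrated in part of each genome. The densest 10% of 100 kb windows held 32.5% of the called sites in E14 and 38.6% in H1. The median window held 54 called sites in E14 (quartiles 21 and 130) and 15 in H1 (quartiles 7 and 32). Of the 23295 E14 windows considered, 2 had no called site, and of the 26621 H1 windows, 597 had none. Across windows, the number of called sites followed the number of listed positions, with a Spearman correlation of 0.918 in E14 and 0.789 in H1, and windows are not independent replicates.

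The densest E14 window was chromosome 8, 122900001 to 123000000, with 704 called sites (exact Poisson interval 653 to 758) at a median level of 19.6% and a median depth of 46. Median depths were 38 to 52 in 9 of the 10 densest E14 windows, beside 30 over all called sites, so their rank by count goes along with depth. The next window along chromosome 8, 123000001 to 123100000, was second with 652, and 119800001 to 119900000 on the same chromosome held 566. Chromosome 2 supplied 4 of the 10 densest windows, all between 165900001 and 169900000, with 540 to 596 called sites. Chromosome 5 supplied the windows 114800001 to 114900000 with 586 and 115000001 to 115100000 with 546, and chromosome 11 the window 117900001 to 118000000 with 634. At the other end, the E14 windows at chromosome 3, 42900001 to 43000000, and chromosome 16, 61600001 to 61700000, had 0 called sites among 624 and 621 listed positions. A single called site each was found on chromosome 12 at 117000001 to 117100000, chromosome 1 at 144800001 to 144900000 and chromosome 8 at 52800001 to 52900000.

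In H1, the densest windows were chromosome 16, 84100001 to 84200000, with 432 called sites (exact Poisson interval 392 to 475), and chromosome 1, 10600001 to 10700000, with 414 (375 to 456). Chromosome 9 supplied 4 of the 10 densest windows, with 298 to 310 called sites, of which 3 lay between 138100001 and 138700000. The rest were on chromosome 17 at 72900001 to 73000000 with 301, chromosome 22 at 41000001 to 41100000 with 283, chromosome 20 at 61500001 to 61600000 with 278 and chromosome 13 at 113800001 to 113900000 with 274. The H1 windows without any call that had the most listed positions were chromosome 1 at 142300001 to 142400000, chromosome 21 at 9700001 to 9800000, chromosome 16 at 44900001 to 45000000 and at 32400001 to 32500000, and chromosome 6 at 57500001 to 57600000. They held 6102 to 8100 listed positions each, beside a median of 3668 per window. No gene annotation of mm9 or hg18 was used here, so the genes in these windows are not named.

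The called sites with the highest lower bound of the interval were the extremes of each list, and their intervals take no account of that selection. In E14, at chromosome 10 position 6830568, chromosome 9 position 95432751 and chromosome 6 position 96404440, all 22 reads kept their C (exact interval 84.6% to 100%). Chromosome 16 position 48431084 had 21 of 21 and chromosome 5 position 41562108 had 20 of 20. The H1 sites ranked in the same way, by the lower bound of the interval, were shallower or lower. Chromosome 1 position 95535380 had 7 of 7 reads (59.04% to 100%), and X position 138463595 had 25 of 34, or 73.5% (55.6% to 87.1%). Positions 10899743 on chromosome 3 and 137396776 on X each had 9 of 10, and position 113223394 on chromosome 11 had 13 of 16. All 10 of these sites were in CG.

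Called CG sites that lay close together also had similar levels, a comparison that was added after the design had been set. Each level was taken relative to the mean of called CG sites of the same depth, and pairs of called sites were correlated across pairs, which are not independent replicates. For sites 2 to 10 bp apart on the same strand, Pearson's r was 0.319 in E14 (interval 0.312 to 0.326) and 0.188 in H1 (0.175 to 0.200). On opposite strands at that distance it was 0.0294 in E14 (0.0187 to 0.0400) and 0.0938 in H1 (0.0774 to 0.110). The dyad partners themselves had r = 0.0318 in E14 and 0.118 in H1, with Spearman's rho of 0.0262 and 0.110. Beyond 150 and up to 200 bp, same-strand r had fallen to 0.0160 in E14 and 0.0183 in H1.

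**Figure D4:**
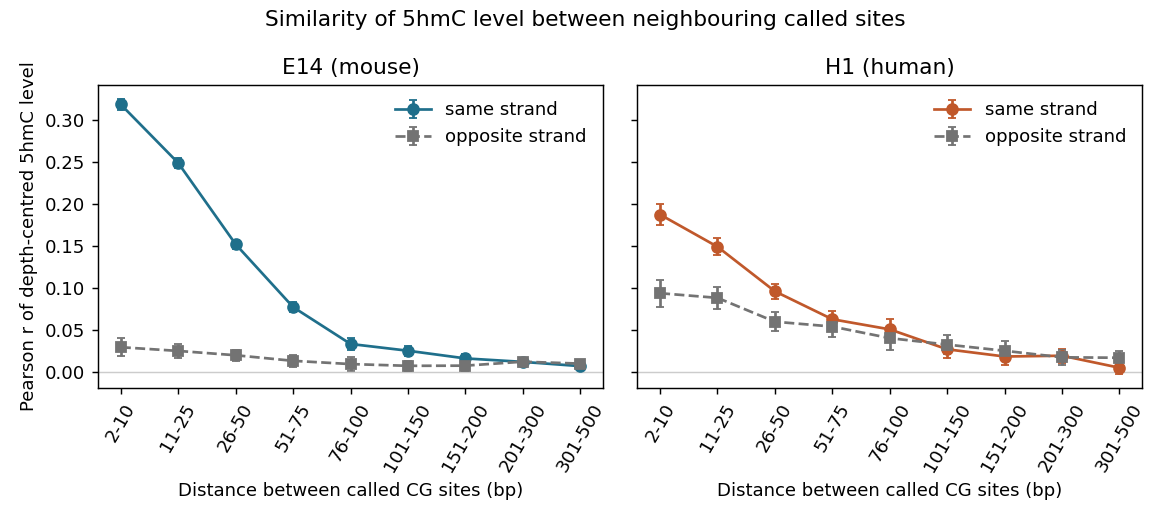
Pearson's r of the depth-centred 5hmC level between pairs of called CG sites (vertical axis) is plotted against their distance (horizontal axis, classes in bp) for pairs on the same strand and on opposite strands in E14 and H1, with 95% interval bars over pairs. Same-strand r at 2 to 10 bp is 0.319 in E14 and 0.188 in H1, and opposite-strand r is lower in both, at 0.0294 and 0.0938.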

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

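Tests of the share outside CG without deep or edge sites, of levels beside sites outside CG, of shared reads, of extra copies of chromosomes 6 and 8 and of site density on those chromosomes were chosen after the results they bear on had been seen at least in part. Other explanations, for the positions at a level of exactly 1, for the H1 levels that differ and for the clustering of called sites, were also tested and then set aside to keep to 3 patterns, and only their measured values are given.

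The strand tracks also differed between strands in E14 and from the called list in H1. In the E14 tracks, 102148 plus-strand positions but 5920 minus-strand positions stood at a level of exactly 1. The plus track held 100% of the 2747 called plus sites with a depth of 4 or less, and the minus track held 0% of the 2661 called minus sites of that depth. Called E14 sites at 100% with a depth of 5 or more were 687 on plus and 747 on minus. At called sites the plus excess was thus absent at these depths, and the depth of uncalled positions is unknown. In H1, 45.3% of the listed called sites had another level in the track than in the called list. The track was the lower at 67.4% of those, with a median difference of -1.62 points, and 6.40% had a level that no part of the reads behind the list can give.

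The share of sites outside CG was larger in E14, 1.29% beside 0.107% in H1. Without sites deeper than 100 reads the shares were 1.29% and 0.106%, which argues against collapsed repeats as the whole cause. Deep sites were 1.55 times as frequent outside CG as in CG in E14, between the bounds set beforehand for and against this cause. Edge calls, at the lowest cytosine count of their depth, were 6.14 percentage points more frequent outside CG in E14, also between the bounds set beforehand. At 3 or more calls above the lowest E14 count of the same depth the shares of the lines were still 1.02% and 0.0404%. This argues against edge calls as the whole cause. Reads that escaped conversion keep their other cytosines, yet at the 5851 E14 sites with listed positions within 10 bp on the same strand those had a median of 0.356 times the level of the site, and the 3664 sites at or under 0.5 alone made a share of 0.180%. This argues against reads that escaped conversion along their length as the whole cause. However, 106 of 26616 E14 sites outside CG had a same-strand neighbour outside CG within 50 bp. That was 1.39 times the 76 with an opposite-strand one, beside 4 and 0 in H1. The E14 ratio lay between the bounds set beforehand for and against escape, so that test did not decide. The other 20765 E14 sites outside CG had no listed position within 10 bp to compare. A methylated cytosine left unoxidised also stays C without affecting its neighbours, so this test cannot decide on that form of escape. At the false discovery rates given with the lists, about 99590 E14 calls and 34709 H1 calls would be false. These exceed the 26616 and 737 calls outside CG, and how false calls divide by context was not measured. False calls, methylated cytosines left unoxidised and the difference between the lines stay open as untested. So do the maps of methylated cytosines that limited each search, and variants of strain 129/Ola against the reference.

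Same-strand neighbours were more alike in level than opposite-strand neighbours in both lines. Thresholds that follow depth were argued against, since with both sites at a depth of 20 to 25 the same-strand excess in r at 2 to 50 bp was 0.258 in E14 and 0.0975 in H1. Reads shared by neighbours on one strand are a candidate explanation, as the excess fell to 0.00864 in E14 and -0.00684 in H1 beyond 150 and up to 200 bp. A short-range strand preference of 5hmC itself may decay in the same way, and no test separated the 2. No comparison of groups in the design bears on it.

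Depth at called E14 sites was higher on chromosomes 6 and 8. Local site density as the whole cause was argued against. Its relation to depth on the other autosomes predicted a median of 70.6% of the observed depth over the 10 Mb segments of these chromosomes. Chromosome 11 had more called sites per Mb than either, 1217, at a median depth of 30. A link between depth and site density as such was not excluded, since median depth was also high in most of the densest E14 windows. Extra copies of both chromosomes in the culture may raise depth along their whole length, and 79.3% of the segments, 23 of 29, had 1.3 to 1.6 times the depth of the other autosomes, short of the 90% set for that explanation. Of the 225 segments on other autosomes, 1 did. Segment depth on chromosomes 6 and 8 ran from 34 to 44, and the median was 1.41 times that of the others, so the explanation stays open, and no karyotype or untreated DNA was analysed here.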

How the results depend on the processing

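The backgrounds for clustering drawn from CpG dyads were chosen after seeing the data. Counts of called sites stayed within 1.5 times under a depth of at least 20 and on autosomes alone. Requiring a depth of at least 20 lowered the share outside CG to 1.11% in E14 and 0.0844% in H1, the median level to 21.7% and 19.2%, the share of called CG sites with a called partner to 10.99% and 19.2%, the number of E14 dyads that differed between strands to 1134, and the X to autosome ratio to 0.0924 and 0.166. The fall in the X ratio follows the lower depth at called X sites. At an adjusted p under 0.01 the number of E14 dyads was 460, and H1 had 0 under each setting of this Fisher's exact test. Pooled reads gave levels of 23.7% in E14 and 20.0% in H1, and depths of 15 to 25 gave 28.6% and 25.0%. On autosomes alone the mean listed level was 11.4% in E14 and 4.40% in H1. Clustering over chance was 1.24 and 2.70 at 500 bp, 2.13 and 7.07 with dyads counted once, and 1.45 and 5.83 for called dyads listed on both strands against all CpG dyads so listed. Earlier forms set every called dyad against that pool, which gave 0.835 in E14, a reversal, and 4.75 in H1 after thinning. Without thinning H1 had 3.28, and E14 had none because its 1691888 background dyads were fewer than the 1894936 to be placed. Only 40.6% of the called E14 dyads and 75.2% of those in H1 belong to that pool, so these earlier forms do not measure clustering, and the cause of the reversal was not tested. The X to autosome ratio per listed position was 0.650 and 0.793. Every alternative kept the E14 share outside CG, median level and mean listed level above those of H1, and the H1 partner share and X ratio above those of E14. These alternatives did not even out the call floors of the lists or the filters of the tracks. The order therefore describes the lists and tracks as deposited. Clustering ratios do not rank the lines. The chance share that limits them was higher in E14 in each form run in both lines. In the forms drawn from dyads listed on both strands, 45.4% of that pool in E14 and 10.6% in H1 also held a called cytosine. This left less room for a high ratio in E14. Not run were a stricter p-value per site, for which no p was used here, a depth of at least 10 in the tracks and partners of that depth whether called or not, since the tracks hold no depth, and all results on annotated features, gene lists and shared genes. No paired analysis was possible because each line had 1 library and no replicates.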

Other observations

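The tests of chromosome ends, of the strand poorer in cytosine and of similarity between neighbours had bounds set before their results were seen, though none was part of the planned results. The split of neighbours by strand at long distance, their values over either strand and the levels relative to sites of the same depth by crowding were added after seeing the results.

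Called sites in H1 were crowded towards the distal end of the chromosomes. The last 5 Mb, at the high-coordinate end, was denser than the rest in 20 of 22 autosomes, with a median ratio of 2.54 and the highest ratio, 6.08, on chromosome 21. Chromosomes 9 and 8 followed with 5.35 and 4.63, while chromosomes 1 and 19 had 0.887 and 0.895. Per listed position 20 of 22 autosomes were also denser, with a median ratio of 1.91. Neither measure is per CpG, although nearly all called sites lay in CG. These ratios therefore do not separate 5hmC at the ends from the density of CpGs there, which was not measured. A two-sided sign-flip permutation test with 100000 resamples gave p = 2e-05 for both measures, the smallest they can give, or 4e-05 after Benjamini-Hochberg adjustment over 4 tests. In E14, 13 of 19 autosomes were denser at that end, with a median ratio of 1.29, and the same permutation test gave p = 0.95, or 0.95 adjusted. Per listed position 11 of 19 were denser, with a median ratio of 1.06 and a permutation p = 0.422, or 0.563 adjusted. Per Mb, chromosomes 15, 4 and 11 had ratios of 2.59, 2.47 and 2.14, and chromosomes 18 and 17 had 0.153 and 0.189. The hypothesis of a denser distal end in both species was set at 75% of autosomes in each with a p under 0.05, and in sites per Mb E14 reached 68.4% beside 90.9% in H1. E14 did not reach that bound by either measure, while the bound against the hypothesis, at most 60% in both lines, was not met either because of H1. Whether the lines differ was not tested.

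Sites in crowded neighbourhoods had slightly higher levels than other called CG sites of the same depth. In E14 the mean difference from sites of the same depth rose from -0.955 percentage points (SE 0.0130) with no other called site within 500 bp to 1.63 points (SE 0.0503) with more than 10. In H1 it rose from -1.01 points (SE 0.0102) to 1.61 points (SE 0.0590). These errors count sites as independent, which neighbours are not. Without regard to depth the E14 medians ran the other way, 25% with none and 23.8% with more than 10. Those most crowded sites were 1.88% of the E14 CG sites and 1.57% of the H1 CG sites.

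The hypothesis that levels of neighbouring called sites are alike at equal depth and lose that likeness with distance did not name a strand, and it met its bounds over pairs on either strand and on the same strand. At 2 to 50 bp, r was 0.157 in E14 and 0.120 in H1 over pairs on either strand, and beyond 1 kb and up to 10 kb it was 0.00825 and 0.00479. Same-strand r was 0.230 and 0.140 at 2 to 50 bp, and 0.00882 and 0.00497 at the long distance. Opposite-strand r at 2 to 50 bp was 0.0236 in E14 and 0.0832 in H1, short of the 0.1 required, so pairs on opposite strands alone did not meet the bounds. The hypothesis that a called cytosine without a called partner lies on the strand poorer in cytosine did not meet its bound. Of the listed positions within 50 bp of such sites, the share on the same strand was 0.544 in E14 and 0.541 in H1, above an even split, where a value below it had been required. That measure counts positions with at least 1 unconverted read and not all cytosines, so a read that escaped conversion may add to the same-strand side. A called site also ensures reads on its own strand, while the strand of an uncalled partner may have few. The measure therefore cannot decide which strand is poorer in cytosine.

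Listed CpG dyads, called or not, differed between the lines in how their strands went together. Over 4403746 H1 dyads listed on both strands, the levels of the strands had r = 0.367 and rho = 0.291. Over 1691888 E14 dyads r was 0.0543 and rho was 0.0565. The E14 minus track leaves out called sites with a depth of 4 or less and the plus track keeps them, while neither H1 track lists called sites of that depth, so the values of the lines do not rest on the same positions. These levels carry no depth and were not corrected for it, and dyads are not independent replicates.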
